A study of Mus musculus with 9 samples.

How the data were processed

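Total RNA from the hippocampi of 9 male mice of 14 months was hybridised to Affymetrix Mouse Gene ST arrays, 1 array per mouse and 3 mice per group, starting from 100 ng of RNA, per the labels' protocols. The labels call the arrays biological replicates. The authors deposited a table of log2 probe-set values for 35557 probe sets, and the scale was inferred as log2 from the values, which lie between 1.12 and 14.76. Affymetrix Expression Console is named in the submitters' processing notes, while its version, the summarization algorithm and the normalization are not given in the sources used here. Array medians lie between 7.19 and 7.28, so genes were not centred, and a difference of 1 is a factor of 2 if the scale is log2. Scanner files were not used here.

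Probe sets were named through GEO's platform annotation. Of 35557 probe sets, 23410 were listed, 21789 of them with 1 gene and 1621 with several, and 12147 were not listed and stay unnamed. Symbols were checked against the GRCm38.p6 gene table by Entrez gene number, and 0 changed. For each of 19938 genes the probe set with the highest mean over the 9 arrays was kept, and 999 genes had several. Of these genes, 19856 were placed in the gene order of GRCm38.p6, and the annotation was used for names and neighbours alone.

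A group-means model was fitted over the 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the 3 groups share their estimate of the spread. Its contrasts were homozygous minus non-Tg, hemizygous minus non-Tg, homozygous minus hemizygous, and the mean of both 3xTg groups minus non-Tg, with a moderated F test over the groups. Adjusted p values are Benjamini-Hochberg over the genes tested, and under 0.05 counts as called. No pseudocount was needed, since the table is on a log scale. Gene lists were fixed before the data were examined: 39 lists with 669 genes, of which 607 were measured, covering brain cell types, tissues that border the hippocampus and pathways. Lists with 5 or more measured genes (37) were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over lists within each contrast. Camera with an estimated correlation and fry are alternatives, and 26 genes belong to more than 1 list. Called genes were compared between chromosomes, and with the neighbourhood of Psen1, by two-sided Fisher's exact tests.

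Genes named in the text follow a rule fixed before the data were examined: App, Mapt, Psen1 and Thy1; for each contrast the 10 largest rises and the 10 largest falls among called genes with arrays that do not overlap, or the 10 smallest p values where fewer than 5 genes were called, leaving out predicted genes; and up to 4 members of smallest p from each list described. The described lists are those that camera called in a contrast, with the amyloid and tau lists in both 3xTg groups against non-Tg.

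The fit was tested on simulated data for 19938 genes with 50 genes changed at each of 4 sizes. In homozygous against non-Tg it recovered 38% of genes changed by 0.3 log2, 66% at 0.5, 96% at 1 and 100% at 2, with 12 false calls. In both 3xTg groups against non-Tg the shares were 58%, 80%, 98% and 100%, with 12 false calls. The simulated noise was independent between genes, and more genes were changed than the real contrasts called. The shares may therefore overstate recovery in the real data. Alternatives were an intensity trend or a robust fit in eBayes, median centring, quantile normalization, genes in the upper 50% by mean, the mean of all probe sets of a gene, all probe sets, array weights, the compared groups alone, a fold of at least 1.5, the replicate number as a block, and each array left out in turn. The choroid plexus score as a covariate and the removal of 2 choroid-rich arrays were added after seeing the data.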

Results

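Gene expression was measured in the hippocampus of 9 male mice at 14 months of age, with 1 Affymetrix Mouse Gene ST array per animal. The 3xTg-AD mouse is a model of Alzheimer's disease that carries human transgenes for mutant amyloid precursor protein and mutant tau, together with a point mutation knocked into the mouse Psen1 gene. Of the 3 groups of 3 arrays, the first came from mice homozygous for the transgenes (homozygous 3xTg), the second from mice with hemizygous transgenes (hemizygous 3xTg) and the third from non-transgenic controls (non-Tg). Mice of both 3xTg groups were homozygous for the Psen1 mutation. The median log2 value over 35557 probe sets was 7.21, 7.24 and 7.28 on homozygous replicates 1, 2 and 3, 7.2, 7.19 and 7.21 on the hemizygous replicates, and 7.19, 7.24 and 7.19 on the non-Tg replicates. Correlations across probe sets between arrays of a group were 0.99 to 0.994, against 0.987 to 0.993 between arrays of different groups. Probe sets are not independent replicates, and the number of arrays limits the precision of every value below.

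Of the genes tied to the transgenes, App read alike in the 3 groups, and 0 of App, Mapt and Thy1 passed over all genes by limma in any contrast. App, which encodes the amyloid precursor protein, had mean log2 values of 12.78 ± 0.01 in homozygous, 12.78 ± 0.02 in hemizygous and 12.79 ± 0.02 in non-Tg mice (SD, n = 3 each). Mapt, which encodes tau, had 10.14 in homozygous, 10.25 ± 0.08 in hemizygous and 10.26 ± 0.03 in non-Tg mice, and its homozygous minus non-Tg change was -0.11 ± 0.05 log2 (SE, limma adjusted p = 0.541), lower in 3 of 3 homozygous arrays than in any non-Tg array. Of all genes tested, 11.33% had arrays without overlap in that contrast, in either direction. Thy1, whose promoter cassette drives the transgenes, read 12.77 ± 0.05 in homozygous, 12.73 ± 0.02 in hemizygous and 12.57 ± 0.07 in non-Tg mice (SD). Its change over both 3xTg groups against non-Tg was 0.18 ± 0.04 log2 (SE), higher in 6 of 6 3xTg arrays, and it did not pass adjustment over all genes (limma adjusted p = 0.237). For both 3xTg groups against non-Tg, 4.73% of all genes had arrays without overlap. Thy1 was the 1 gene of the 3 that passed adjusted over the list alone, in each 3xTg group and in both together against non-Tg. These probes were designed on mouse sequence, so App and Mapt do not test for the presence of the human transgenes. Psen1 had no probe set in the gene table used and was not analysed here. The Y-linked genes Eif2s3y, Kdm5d and Uty read between 8.39 and 9.43 on every array, and Xist read between 4.97 and 5.15, as in male tissue.

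**Figure D1:**
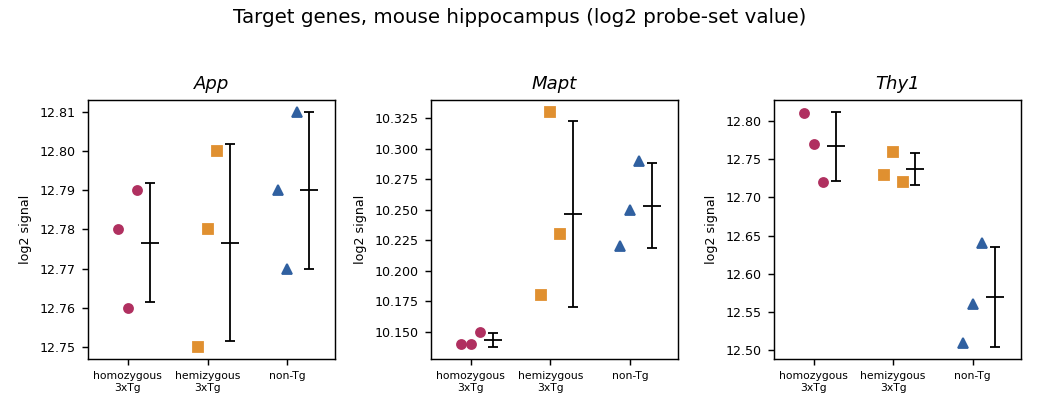
Log2 probe-set values of App, Mapt and Thy1 (y axis) in the 3 groups (x axis), with 1 point per array and a bar for the mean ± SD (n = 3). App lies at 12.78 to 12.79 in the group means, and the Thy1 means are 12.77, 12.73 and 12.57.

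In homozygous 3xTg mice compared with non-Tg mice, the question was which hippocampal genes differ when the transgenes are present in full dose. Snapc1, a subunit of the complex that activates small nuclear RNA promoters, fell by 0.71 ± 0.04 log2 (SE, n = 3 and 3) to a ratio of 0.611, and was lower in 3 of 3 homozygous arrays than in any non-Tg array (limma adjusted p = 4.4e-04). Such a lack of overlap, in either direction, held for 11.33% of all genes. Eps8l1, a relative of the actin regulator Eps8, fell by 0.85 ± 0.06 log2 (adjusted p = 0.00284), and Pygb, the brain form of glycogen phosphorylase, fell by 0.37 ± 0.04 log2 (adjusted p = 0.0354). These were the 3 genes past the threshold among 19938 tested, with 0 higher and 3 lower. By limma, 700 genes were higher and 1062 lower at an unadjusted p under 0.05. The count depended on the fit: in the upper 50% of genes by mean 40 passed (12 higher and 28 lower), with an intensity trend 11 (3 higher and 8 lower), and after quantile normalization 5. Without the 2 arrays richest in choroid plexus genes (choroid-rich arrays, homozygous replicate 1 and non-Tg replicate 3), an alternative chosen after the results were seen, it was 1. Next in order of p were Kcnf1 (-0.61 ± 0.07 log2, adjusted p = 0.0538), Zfp804a (0.36 ± 0.04, adjusted p = 0.0538), Cstad (0.55 ± 0.06, adjusted p = 0.0549), Bfsp2 (-0.52 ± 0.06, adjusted p = 0.0595), Tdp1 (-0.54 ± 0.07, adjusted p = 0.0643), Fis1 (-0.37 ± 0.05, adjusted p = 0.0643) and Churc1 (-0.71 ± 0.09, adjusted p = 0.0939).

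Among the gene lists, 6 of 37 passed camera with a preset correlation in this comparison, and 0 passed with a correlation estimated per list, where 0 had an unadjusted p under 0.05 and the smallest adjusted p was 0.832. All 20 interferon response genes measured had positive changes (median 0.17 log2, camera adjusted p = 4.2e-06, adjusted p = 0.832 with an estimated correlation), among them Rsad2 (0.18 ± 0.05), Oasl2 (0.43 ± 0.18) and Oas1a (0.26 ± 0.11). By limma 0 of them passed over all genes or adjusted over the list alone, and 3 were higher at an unadjusted p under 0.05. Of 14 complement genes, 11 had positive changes (median 0.12, camera adjusted p = 0.00728, adjusted p = 0.832 with an estimated correlation). C1qb (0.36 ± 0.07, adjusted p = 0.181) and C1qc (0.31 ± 0.07, adjusted p = 0.27), chains of the complement initiator C1q, were the 2 that passed adjusted over the list alone, and 0 passed over all genes (4 higher at an unadjusted p under 0.05). Of 23 disease-associated microglia genes, 18 had positive changes (median 0.05, camera adjusted p = 0.0304, adjusted p = 0.832 with an estimated correlation). The lysosomal protease gene Ctss (0.19 ± 0.04, adjusted p = 0.225) and Cst7 (0.64 ± 0.15, adjusted p = 0.278) were the 2 that passed adjusted over the list alone, and 0 passed over all genes (3 higher at an unadjusted p under 0.05). Immediate early genes (17 of 20 positive, median 0.1, camera adjusted p = 0.0187) included Egr2 at 0.37 ± 0.14 and Fosb at -0.16 ± 0.06. Endothelial genes (13 of 14 positive, median 0.11, camera adjusted p = 0.0187) included Esam at 0.23 ± 0.12. Markers of neighbouring cortex (12 of 14 negative, median -0.06, camera adjusted p = 0.0255) included Ccn2 at -0.7 ± 0.23 and Tbr1 at -0.27 ± 0.1. For these last 3 lists 0 genes passed over all genes or adjusted over the list alone, against 3, 0 and 4 at an unadjusted p under 0.05. The adjusted p was 0.832 with an estimated correlation for each. Homozygous replicate 1 had the highest mean deviation of the 9 arrays for interferon response (0.269), complement (0.27), endothelial (0.352), immediate early (0.289) and meningeal genes (0.52), and 1.186 for choroid plexus genes. Without homozygous replicate 1 the adjusted p was 0.348 for complement, 0.665 for disease-associated microglia, 0.446 for immediate early genes and 0.763, with the direction turned, for endothelium. Other arrays also ended calls. Immediate early genes gave 0.134 without non-Tg replicate 1 and 0.0796 without non-Tg replicate 2. Without non-Tg replicates 2 and 3, disease-associated microglia gave 0.184 and 0.12, and endothelium gave 0.051 and 0.0521. The cortical markers gave 0.232, 0.134 and 0.0521 without homozygous replicate 3, non-Tg replicate 1 and non-Tg replicate 3. Without the 2 choroid-rich arrays together the adjusted p was 0.983 for disease-associated microglia, 0.433 for complement, 0.063 for immediate early genes and 0.776, with the direction turned, for endothelium. Over their alternatives the adjusted p spanned 3.4e-08 to 0.832 for interferon response, 1.5e-05 to 0.832 for complement, 3.1e-04 to 0.983 for disease-associated microglia, 9.6e-07 to 0.832 for immediate early genes, 1.8e-04 to 0.832 for endothelium and 0.00227 to 0.832 for cortical markers.

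In hemizygous 3xTg mice compared with non-Tg mice, which differ from controls by a lower transgene dose and the same Psen1 mutation, 6 genes passed the threshold. Ly86, a partner of a Toll-like receptor relative on immune cells, rose by 0.93 ± 0.1 log2 (SE, n = 3 and 3, limma adjusted p = 0.0459) to a ratio of 1.9, and Ctss rose by 0.36 ± 0.04 log2 (adjusted p = 0.0459). Eps8l1 fell by 0.85 ± 0.06 (adjusted p = 0.00288) and Snapc1 fell by 0.71 ± 0.04 (adjusted p = 4.7e-04). Slc38a6, of an amino acid transporter family, fell by 0.56 ± 0.06 (adjusted p = 0.0394), and Bfsp2 fell by 0.55 ± 0.06 (adjusted p = 0.0459). Each of the 6 had its direction in 3 of 3 hemizygous arrays against every non-Tg array, as did 11% of all genes in either direction. Without hemizygous replicate 2 the count was 4, without homozygous replicate 2 it was 3, and without homozygous replicate 1 or 3, hemizygous replicate 1 or 3, or non-Tg replicate 1, 2 or 3 it was 2. It was 11 with an intensity trend (5 higher and 6 lower), 3 with a robust fit, 2 over all probe sets or the compared groups alone, and 1 without the 2 choroid-rich arrays.

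The lists gave 10 of 37 calls by camera in hemizygous against non-Tg mice and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05 and the smallest adjusted p was 0.616. Of 21 unfolded protein response genes, which encode chaperones and enzymes of the endoplasmic reticulum, 19 had positive changes (median 0.11, camera adjusted p = 1.2e-06, adjusted p = 0.616 with an estimated correlation), including Sdf2l1 (0.49 ± 0.15), Manf (0.24 ± 0.08), Hspa5 (0.22 ± 0.08) and Xbp1 (0.23 ± 0.09). All 13 heat shock genes had positive changes (median 0.1, camera adjusted p = 1.1e-05, adjusted p = 0.616 with an estimated correlation), including Chordc1 (0.33 ± 0.1) and Hsp90aa1 (0.11 ± 0.04). In both of these lists 0 genes passed by limma over all genes or adjusted over the list alone, against 6 and 2 higher at an unadjusted p under 0.05. Over their alternatives the adjusted p spanned 3.7e-08 to 0.623 and 1.1e-09 to 0.616. Complement genes (11 of 14 positive, median 0.18, camera adjusted p = 8.5e-05, adjusted p = 0.636 with an estimated correlation) included C1qb (0.45 ± 0.07), C1qc (0.39 ± 0.07), C3ar1 (0.61 ± 0.16) and C1qa (0.24 ± 0.08). These were the 4 genes that passed adjusted over the list alone, against 0 over all genes and 6 higher at an unadjusted p under 0.05 (adjusted p of the list 7.7e-06 to 0.636 over its alternatives). Homeostatic microglia genes (14 of 15 positive, median 0.1, camera adjusted p = 8.5e-05, adjusted p = 0.616 with an estimated correlation) included Csf1r (0.17 ± 0.06) and Olfml3 (0.33 ± 0.08), the 1 gene that passed adjusted over the list alone, with 0 over all genes and 3 at an unadjusted p under 0.05. The adjusted p of this list spanned 8.8e-06 to 0.623 over its alternatives. Disease-associated microglia genes (16 of 23 positive, median 0.04, camera adjusted p = 0.00381, adjusted p = 0.858 with an estimated correlation) included Ctss, the 1 that passed over all genes. Adjusted over the list alone 3 passed, which were Ctss, Cst7 (0.54 ± 0.15) and Tyrobp (0.27 ± 0.07). Its call ended without non-Tg replicate 2 (adjusted p 0.0895) or non-Tg replicate 3 (0.0567), within a span of 1.7e-04 to 0.858 over its alternatives. Glutamatergic synapse genes (16 of 20 positive, median 0.04, camera adjusted p = 0.0024, 0 genes past either adjustment) gave an adjusted p of 0.616 with an estimated correlation, in a span of 0.00177 to 0.616. CA3 and CA2 pyramidal cell markers (11 of 13 positive, median 0.04, camera adjusted p = 0.0299, 0 genes past either adjustment) gave 0.616 with an estimated correlation, and 0.104, 0.165 and 0.0704 without hemizygous replicate 2, non-Tg replicate 2 and non-Tg replicate 3, and 0.0793 without the 2 choroid-rich arrays (span 0.0127 to 0.616). Of the synapse and CA3 genes 0 and 1 had an unadjusted p under 0.05. Glucocorticoid response genes (10 of 14 positive, median 0.06, camera adjusted p = 0.0471, 0 genes past either adjustment and 1 unadjusted) included Mt2 (0.19 ± 0.07) and gave an adjusted p of 0.858 with an estimated correlation. The call was lost without homozygous replicates 1, 2 and 3 (0.0566, 0.0529 and 0.0559), hemizygous replicates 1 and 3 (0.0846 and 0.885) and non-Tg replicate 2 (0.741), in a span of 2.3e-05 to 0.885.

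Choroid plexus and meningeal genes were lower in the same comparison, while thalamus, striatum, cortical and ependyma lists were not called (adjusted p 0.59, 0.717, 0.419 and 0.21). All 16 choroid plexus genes had negative changes (median -0.63, camera adjusted p = 0.0024, adjusted p = 0.858 with an estimated correlation), with 0 genes past either adjustment by limma and 1 lower at an unadjusted p under 0.05. All 17 meningeal and vascular fibroblast genes had negative changes (median -0.25, camera adjusted p = 9.2e-04, adjusted p = 0.858 with an estimated correlation), among them Dcn (-0.42 ± 0.1, also a member of the CA1 list), the 1 gene that passed adjusted over the list alone and the 1 at an unadjusted p under 0.05, with 0 over all genes. The choroid plexus genes had a mean deviation of 1.375 on non-Tg replicate 3 and between -0.515 and -0.288 on the hemizygous arrays. Without non-Tg replicate 3 the choroid plexus adjusted p was 0.659, and without the 2 choroid-rich arrays 0.258 (span 6.1e-06 to 0.931 over its alternatives), and without non-Tg replicate 1 the meningeal adjusted p was 0.0646 (span 2.6e-06 to 0.858).

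Homozygous and hemizygous 3xTg mice both carry the Psen1 mutation, so the contrast between them sets transgene dose apart. By limma, 0 of 19938 genes passed, and 989 genes had an unadjusted p under 0.05 where 997 are expected by chance. Cstad had the smallest p, at 8.66 ± 0.02 in homozygous and 8.09 ± 0.11 in hemizygous mice (SD), a difference of 0.57 ± 0.06 log2 (SE, adjusted p = 0.248). Alkbh3, a DNA repair dioxygenase, differed by 0.3 ± 0.04 (adjusted p = 0.881), and the serotonin receptor genes Htr1a and Htr1b by -0.39 ± 0.07 and -0.24 ± 0.05 (adjusted p = 0.914 each). The Fc receptor gene Fcgr3 differed by -0.56 ± 0.12 (adjusted p = 0.914).

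The lists gave 8 of 37 calls by camera between the 3xTg groups, and 0 with an estimated correlation, where 1 had an unadjusted p under 0.05 and the smallest adjusted p was 0.712. By limma 0 genes of these 8 lists passed over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 11 unfolded protein response genes, 2 each for heat shock, immediate early genes, interferon response and cholesterol synthesis, 1 for oxidative phosphorylation, and 0 for choroid plexus and pericytes. Unfolded protein response genes were lower in homozygous than in hemizygous mice in 18 of 21 cases (median -0.16 log2, camera adjusted p = 2.5e-10, adjusted p = 0.712 with an estimated correlation), with Pdia4 at -0.35 ± 0.09, Hspa5 at -0.28 ± 0.08, Sdf2l1 at -0.5 ± 0.15 and Manf at -0.26 ± 0.08. A 2nd Pdia4 probe set with a mean of 6.02 changed by 0.25 in homozygous and -0.05 in hemizygous against non-Tg mice, where the one used (mean 10.45) changed by -0.12 and 0.23, so its probe sets disagree. Heat shock genes were lower in 13 of 13 cases (median -0.1, camera adjusted p = 9.0e-06, adjusted p = 0.712 with an estimated correlation), with Hspa1a at -0.27 ± 0.09. Oxidative phosphorylation genes were lower in 25 of 28 cases by a median of -0.02 (camera adjusted p = 0.0118, adjusted p = 0.746 with an estimated correlation). Interferon response genes were higher in homozygous mice (19 of 20 positive, median 0.16, adjusted p = 3.1e-04), with Irf7 at 0.28 ± 0.09 and Stat2 opposed at -0.26 ± 0.07. Immediate early genes were higher too (17 of 20, median 0.17, adjusted p = 9.7e-05), with Egr2 at 0.48 ± 0.14. So were choroid plexus genes (16 of 16, median 0.45, adjusted p = 8.7e-04) and pericyte and smooth muscle genes (12 of 13, median 0.08, adjusted p = 0.011). Cholesterol synthesis genes (15 of 17, median 0.03, adjusted p = 0.00303) included Insig1 at 0.18 ± 0.07. With an estimated correlation the adjusted p was 0.746 for choroid plexus and 0.712 for the other 4. Without homozygous replicate 1, whose choroid plexus deviation was 1.186, the adjusted p was 0.0744 for interferon response, 0.0746 for immediate early genes, 0.557 for choroid plexus and 0.557 for pericytes and smooth muscle, which also gave 0.0907 without hemizygous replicate 3. Without the 2 choroid-rich arrays it was 0.072 for interferon response, 0.0698 for choroid plexus and 0.572 for pericytes and smooth muscle. Oxidative phosphorylation gave 0.101, 0.143 and 0.0534 without homozygous replicate 2, homozygous replicate 3 and hemizygous replicate 2, and cholesterol synthesis gave 0.13 without homozygous replicate 2. Over the alternatives the adjusted p spanned 1.0e-12 to 0.712 for the unfolded protein response, 1.1e-10 to 0.712 for heat shock, 6.9e-04 to 0.746 for oxidative phosphorylation, 1.3e-09 to 0.712 for interferon response, 6.2e-11 to 0.712 for immediate early genes, 5.1e-06 to 0.903 for choroid plexus, 3.1e-05 to 0.712 for cholesterol synthesis and 4.4e-04 to 0.712 for pericytes.

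The 6 arrays of both 3xTg groups against the 3 non-Tg arrays give the mean change of the 2 groups, which 1 group alone can carry. In this contrast 15 genes passed, 5 higher and 10 lower. The largest rise was Gpr137b-ps at 1.01 ± 0.12 log2 (SE, adjusted p = 0.0439), annotated as a pseudogene, so signal from related genes cannot be ruled out. Ly86 rose by 0.82 ± 0.09 (adjusted p = 0.0366), Adi1, an enzyme of methionine salvage, by 0.71 ± 0.08 (adjusted p = 0.0366), Ctss by 0.28 ± 0.03 (adjusted p = 0.0439) and Zfp804a by 0.27 ± 0.03 (adjusted p = 0.0481). The largest fall was Mamdc2, which fell by 1.16 ± 0.14 to a ratio of 0.448 (adjusted p = 0.0439). Eps8l1 fell by 0.85 ± 0.05 (adjusted p = 8.7e-04), Snapc1 fell by 0.71 ± 0.03 (adjusted p = 1.4e-04), Churc1 fell by 0.71 ± 0.08 (adjusted p = 0.0366), and the potassium channel subunit gene Kcnf1 fell by 0.53 ± 0.06 (adjusted p = 0.0366). Bfsp2 fell by 0.53 ± 0.05 (adjusted p = 0.0274), the DNA repair gene Tdp1 fell by 0.46 ± 0.06 (adjusted p = 0.0481), Slc38a6 fell by 0.43 ± 0.05 (adjusted p = 0.0366), Pygb fell by 0.33 ± 0.03 (adjusted p = 0.0274) and the mitochondrial fission gene Fis1 fell by 0.32 ± 0.04 (adjusted p = 0.0439). A 2nd Tdp1 probe set with a mean of 6.72 changed by 0.01, so its probe sets disagree. The count was 2 without homozygous replicate 1 or hemizygous replicate 3, 3 without homozygous replicate 3, hemizygous replicate 1 or 2 or non-Tg replicate 1, and 4 without homozygous replicate 2 or non-Tg replicate 2 or 3. Leaving out homozygous replicate 1 and non-Tg replicate 3 together left 1, all probe sets gave 4, and the upper 50% of genes by mean gave 24 (9 higher and 15 lower). The moderated F test over the 3 groups passed 2 genes, Eps8l1 and Snapc1. It passed 1 without non-Tg replicate 2 or 3, 0 without the 2 choroid-rich arrays, 15 with an intensity trend and 13 in the upper 50% by mean.

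**Figure D2:**
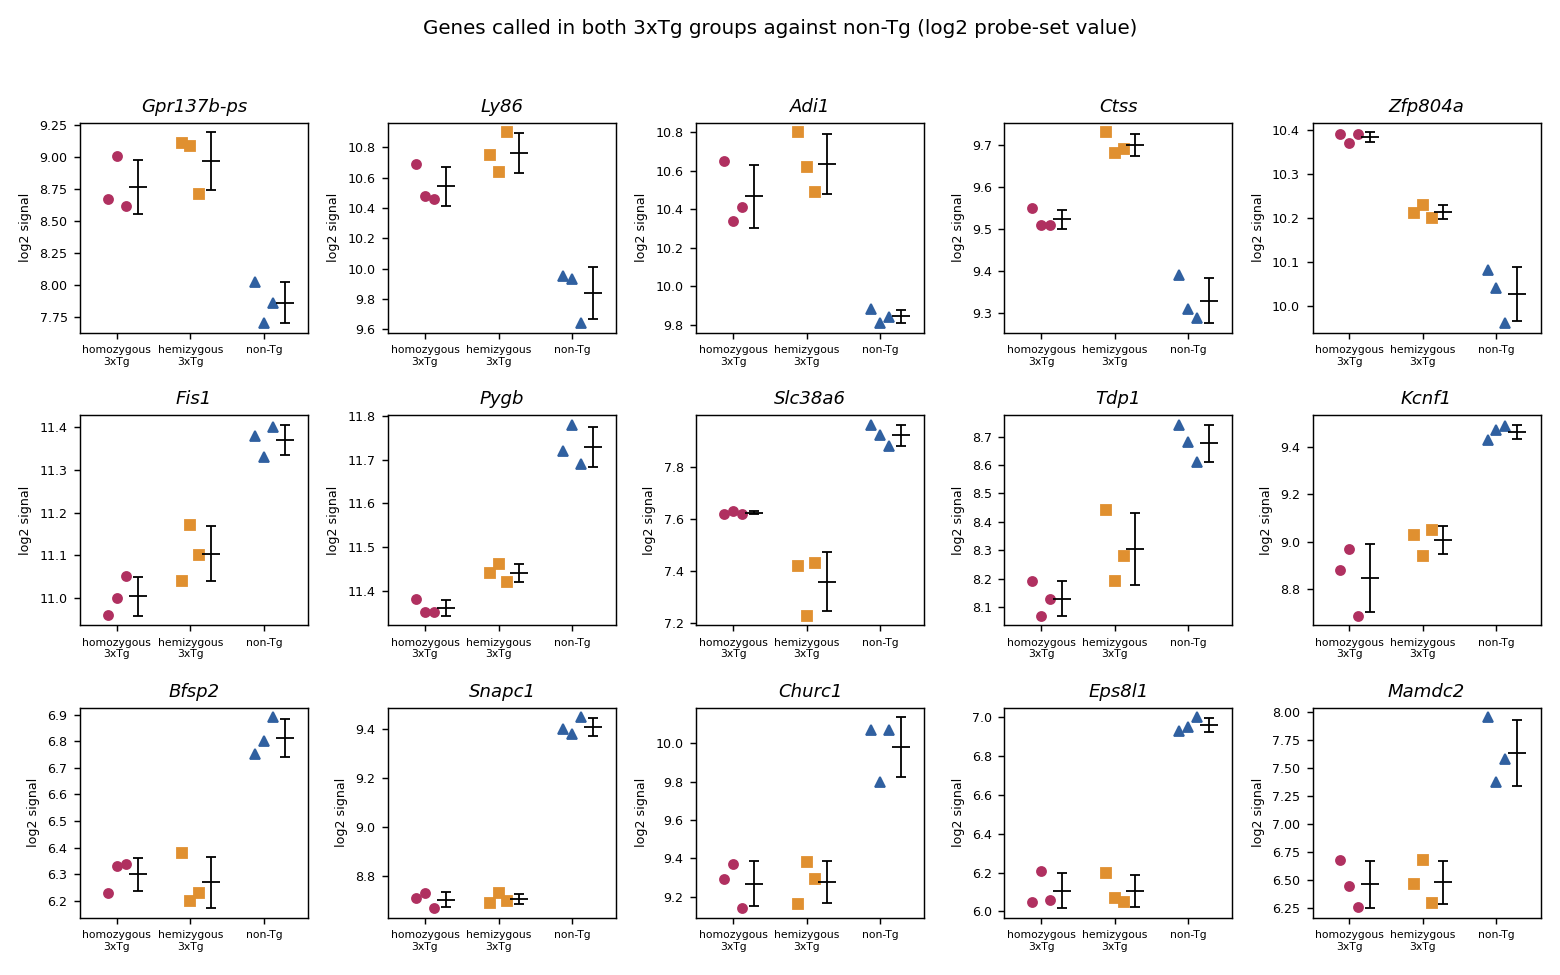
Log2 probe-set values (y axis) of the 15 genes called in both 3xTg groups against non-Tg, per group (x axis), with 1 point per array and a bar for the mean ± SD (n = 3). Snapc1 means are 8.7, 8.71 and 9.41, and Mamdc2 means are 6.46, 6.49 and 7.63, in homozygous, hemizygous and non-Tg mice.

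In both 3xTg groups against non-Tg camera called 10 of 37 lists, among them complement and microglial genes. With an estimated correlation 0 were called, 2 had an unadjusted p under 0.05 and the smallest adjusted p was 0.904. Complement genes (11 of 14 positive, median 0.15, camera adjusted p = 5.5e-04) included C1qb (0.4 ± 0.06, adjusted p = 0.103), C1qc (0.35 ± 0.06), C3ar1 (0.53 ± 0.14) and C1qa (0.22 ± 0.07), which were the 4 genes that passed adjusted over the list alone, with 0 over all genes. Homeostatic microglia genes (11 of 15 positive, median 0.07, camera adjusted p = 0.00226) had 1 such gene, Olfml3 (0.38 ± 0.07), and 0 over all genes. Disease-associated microglia genes (17 of 23 positive, median 0.05, camera adjusted p = 0.00773) had 3 adjusted over the list alone, Ctss, Cst7 (0.59 ± 0.13) and Tyrobp (0.23 ± 0.06), and 1 over all genes. Reactive astrocyte genes (15 of 21 positive, median 0.08, camera adjusted p = 0.0426) had 1, the acute phase gene Serpina3n (0.35 ± 0.08), with Osmr at 0.44 ± 0.17 and S100a10 opposed at -0.23 ± 0.07, and 0 over all genes. Interferon response genes (17 of 20 positive, median 0.09, camera adjusted p = 0.00147) had 1, Stat2 (0.28 ± 0.06), and 0 over all genes. At an unadjusted p under 0.05, complement and homeostatic microglia had 4 genes each, reactive astrocytes 5 and interferon response 2. The glutamatergic synapse (17 of 20 positive, median 0.03, adjusted p = 0.00776), heat shock (12 of 13, median 0.05, adjusted p = 0.0134), endothelium (12 of 14, median 0.07, adjusted p = 0.0426) and unfolded protein response lists (15 of 21, median 0.04, adjusted p = 0.045) were also called, and meningeal and vascular fibroblast genes were lower in 17 of 17 cases (median -0.18, adjusted p = 0.0117). In these last 5 lists 0 genes passed either adjustment, and 1 heat shock and 1 meningeal gene had an unadjusted p under 0.05. Some calls were carried by 1 group. Unfolded protein response genes were positive against non-Tg in 6 of 21 cases in homozygous (median -0.05) and 19 of 21 in hemizygous mice (0.11). For heat shock it was 7 of 13 (median 0) and 13 of 13 (0.1), and for interferon response 20 of 20 (0.17) and 12 of 20 (0.01). With an estimated correlation each of the 10 lists had an adjusted p of 0.904, the highest over its alternatives. Without the 2 choroid-rich arrays 7 of these calls ended, with an adjusted p of 0.382 for disease-associated microglia, 0.114 for homeostatic microglia, 0.114 for interferon response, 0.649 for reactive astrocytes, 0.694 for endothelium, 0.512 for the unfolded protein response and 0.597 for heat shock. Single arrays ended 7 calls. The adjusted p was 0.0953 for disease-associated microglia, 0.246 for reactive astrocytes, 0.765 for endothelium, 0.254 for the unfolded protein response and 0.083 for heat shock without homozygous replicate 1. It was 0.0724 for reactive astrocytes and for endothelium without hemizygous replicate 1, and 0.172 and 0.0582 for the unfolded protein response and heat shock without hemizygous replicate 3. Without non-Tg replicate 1 it was 0.0544 for the glutamatergic synapse, 0.0879 for endothelium and 0.28 for meningeal genes, which also gave 0.062 and 0.0583 without homozygous replicates 2 and 3. Without non-Tg replicate 2 it was 0.102 for disease-associated microglia, 0.131 for reactive astrocytes, 0.0961 for endothelium, 0.477 for the unfolded protein response and 0.0961 for heat shock. Without non-Tg replicate 3 it was 0.199 for reactive astrocytes, 0.0931 for endothelium, 0.109 for the unfolded protein response and 0.199 for heat shock. The lowest adjusted p over the alternatives was 9.4e-06 for complement, 4.7e-05 for homeostatic microglia, 2.2e-04 for disease-associated microglia, 0.00835 for reactive astrocytes, 1.2e-04 for interferon response, 0.00412 for the glutamatergic synapse, 3.7e-04 for heat shock, 0.00223 for endothelium, 0.0028 for the unfolded protein response and 2.8e-07 for meningeal genes. Choroid plexus genes had mean deviations of 0.179 ± 0.873 in homozygous, -0.419 ± 0.117 in hemizygous and 0.239 ± 0.997 in non-Tg mice (SD, n = 3 each).

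**Figure D3:**
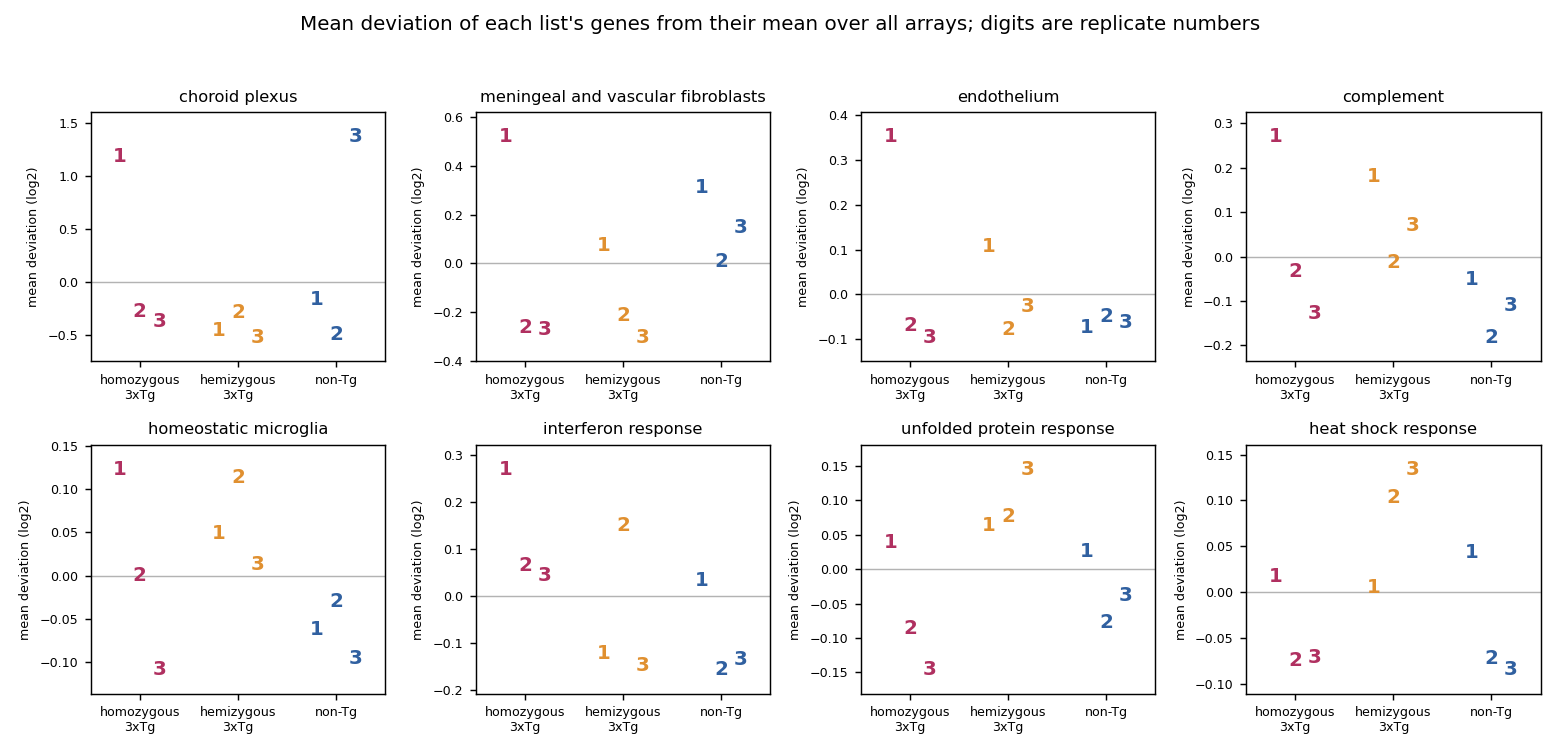
Mean deviation of a list's genes from their means over the 9 arrays (y axis, log2) for 8 gene lists in the 3 groups (x axis), with each array drawn as its replicate number. Homozygous replicate 1 (1.186) and non-Tg replicate 3 (1.375) stand above the other arrays for choroid plexus, and the hemizygous mean for the unfolded protein response is 0.095 against -0.064 in homozygous and -0.031 in non-Tg mice.

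Genes of amyloid and tau biology were set apart in advance, as the targets of the model. Of 25 genes of amyloid processing and clearance, 13 had positive and 12 negative changes in both 3xTg groups against non-Tg (median 0, camera adjusted p = 0.396). Ide, which encodes an insulin- and amyloid-degrading protease, read 10.19 ± 0.2 in homozygous, 10.18 ± 0.02 in hemizygous and 9.65 ± 0.05 in non-Tg mice (SD), a change of 0.54 ± 0.08 log2 (SE, limma adjusted p = 0.0864). It was the 1 gene of its list that passed adjusted over the list alone. Of 23 genes for tau and its kinases and phosphatases, 12 had positive and 11 negative changes (median 0, camera adjusted p = 0.522), and 0 passed either adjustment by limma, with 1 at an unadjusted p under 0.05. Ppp3ca, a catalytic subunit of calcineurin, was at 0.08 ± 0.03. With an estimated correlation the adjusted p was 0.904 for both lists.

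The knock-in lies in Psen1 on chromosome 12, so the positions of called genes were compared with the order of genes in the GRCm38.p6 annotation. Of the 15 genes called in both 3xTg groups against non-Tg, 6 lie on chromosome 12, which holds 652 of the 19856 genes placed, where 0.49 are expected (two-sided Fisher's exact test p = 4.8e-06, adjusted over chromosomes 1.0e-04). They are Kcnf1, Adi1, Slc38a6, Snapc1, Churc1 and Tdp1. In homozygous and in hemizygous against non-Tg alone, 1 of 3 and 2 of 6 called genes lie there (Fisher's exact p = 0.0953 and 0.0148, adjusted over chromosomes 1 and 0.325). In gene order, Kcnf1 lies 281 measured genes before Psen1, Adi1 243, Slc38a6 75, Snapc1 70 and Churc1 48, and Tdp1 lies 95 after it. Among the 50 measured genes nearest to Psen1, 0 were called where 0.04 are expected (exact p = 1), among the 100 nearest 1 was (0.08 expected, exact p = 0.073), and among the 200 nearest 4 were (0.15 expected, exact p = 1.2e-05). For the 100 nearest the exact p was 0.02 without non-Tg replicate 2, 1 without any other array or without the 2 choroid-rich arrays, and 0.0239 in the upper 50% of genes by mean. For called genes on chromosome 12, both 3xTg groups against non-Tg, 5 arrays ended the call when left out, with 1 gene left: p was 0.0646 without homozygous replicate 1 or hemizygous replicate 3, 0.0953 without hemizygous replicate 1 or non-Tg replicate 1, and 0.125 without non-Tg replicate 3, in a range of 0.00147 to 0.125 over the alternatives.

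**Figure D4:**
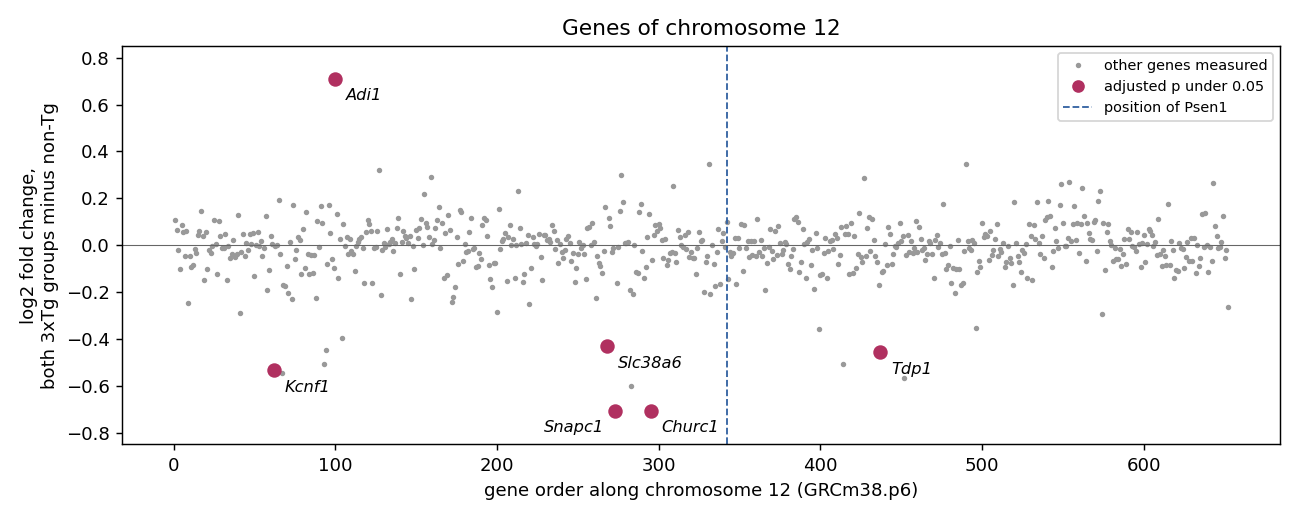
Log2 fold change of both 3xTg groups minus non-Tg (y axis) for 652 genes of chromosome 12 in gene order (x axis), with the 6 genes at adjusted p under 0.05 named and the position of Psen1 marked by the dashed line. Of the 6 named genes, Adi1 lies above 0 at 0.71 and the others lie below it.

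The homozygous and hemizygous contrasts share the non-Tg arrays, so their similarity was set against simulated unchanged groups. The log2 fold changes correlated across genes at r = 0.602, against 0.5 ± 0.0228 in 100 simulations (SD), and genes are not independent replicates. The simulated noise was independent between genes, while real genes vary together, so this SD may be too narrow to judge the excess. The signs of the fold changes were the same for 70.6% of genes, against 66.7% simulated. The covariance was 0.00726 against 0.00479 simulated, a difference of 0.00247. Since 3 controls cannot be split into parts of at least 2, part of the excess may come from the shared controls. Eps8l1 and Snapc1 were the 2 genes called lower in both contrasts, of 3 and 4 called lower, and the shared controls favour such overlap. For the 15 genes called in both 3xTg groups against non-Tg, the ratio of the hemizygous to the homozygous change had a median of 0.99 and a range of 0.53 for Zfp804a to 1.9 for Ctss. These genes were chosen by the mean of the 2 changes, which share the non-Tg arrays, so similar sizes are favoured. Between the 3xTg groups 5 of the 15 had an unadjusted p under 0.05, against 989 of all 19938 genes, with none at an adjusted p under 0.05. The choice also favours genes of small spread, which lowers such p values. Without a 3xTg array r was 0.536 to 0.581, where unchanged groups of equal spread would give 0.447, and without a non-Tg array it was 0.647 to 0.705, where they would give 0.6.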

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

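The tests of the 3 patterns below were chosen after the results were seen, while the counts over other splits of the arrays were set before them. For both 3xTg groups against non-Tg, 100 splits of the 9 arrays were sampled, the real one included. Of these, 1 called as many as the real 15 genes, and the highest other count was 10. This argues against chance for that count but does not exclude it. For the F test 2 of 100 splits reached 2 genes, the highest other being 2. Another split did as well as the real one there, so chance is not excluded. In pairwise comparisons 10 splits exist, too few for a share under 0.05: 1 split reached the real 3 genes in homozygous against non-Tg (highest other 0), 1 reached 6 in hemizygous against non-Tg (highest other 0), and 10 reached 0 between the 3xTg groups (highest other 1). For lists, 8 splits reached the real 6 in homozygous against non-Tg (highest other 13), 1 reached 10 in hemizygous against non-Tg (highest other 8) and 8 reached 8 between the 3xTg groups (highest other 17). For both 3xTg groups against non-Tg, 38 of 100 splits called as many as 10 lists, with up to 20, so chance is not excluded for that list count.

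Lists called by camera in homozygous against hemizygous mice are candidates for a difference between the 2 transgene doses. The adjusted p was 2.5e-10 for the unfolded protein response, 9.0e-06 for heat shock, 9.7e-05 for immediate early genes, 3.1e-04 for interferon response, 8.7e-04 for choroid plexus, 0.00303 for cholesterol synthesis, 0.011 for pericytes and smooth muscle and 0.0118 for oxidative phosphorylation. With an estimated correlation none of these 8 calls held. An exact permutation test of each list mean over arrays gave p = 0.1 for the unfolded protein response, the smallest it allows. It gave p of 0.2 to 0.4 for the other lists. As many lists were called in 8 of 10 splits of these arrays, with up to 17, so a difference by dose is not shown. In probe sets with no gene in the annotation used, 2 passed in both 3xTg groups against non-Tg when all 35557 probe sets were tested. Probe set 10338939 changed by -3.32 ± 0.29 log2 (SE, limma adjusted p = 0.0428), with means of 2.35, 2.23 and 5.61 in homozygous, hemizygous and non-Tg mice. Its 3xTg means lie near the lowest value of the table (1.12), so signal above background is not shown there and the size of the change is uncertain. Probe set 10342618 changed by -1.56 ± 0.13 (adjusted p = 0.0327), with means of 8.33, 8.57 and 10.01.

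Of the genes called in both 3xTg groups against non-Tg, 6 lay on chromosome 12, the chromosome of the Psen1 knock-in. The real split alone gave as many among 100 splits (highest other 3), the lowest share these splits allow. That count can rise with the number of genes called, which was 15 in the real split and at most 10 in the others. The splits therefore add little about the cluster itself, and chance is not excluded. Leaving out some single arrays left 1 called gene there. For these 6 genes the hemizygous change exceeded 50% of the homozygous one by 0.31 ± 0.15 log2 (SD over the 6 genes). This goes against a change in proportion to transgene copy number, with a limit. The genes were chosen by a contrast that includes the hemizygous arrays, and both changes share the non-Tg arrays, which favours similar sizes. Without the 2 choroid-rich arrays the mean size over the 6 genes was 0.58 against 0.59, so it did not depend on those arrays. DNA of another strain carried along with the knock-in may explain the cluster: among uncalled genes of the chromosome 6 had an unadjusted p under 0.001 where 2.7 are expected (Fisher's exact p = 0.0535), which leaves it open. Positions were mixed: 0 of the 50, 1 of the 100 and 4 of the 200 measured genes nearest to Psen1 were called. Kcnf1 and Adi1 lie 281 and 243 measured genes before it. Probes that mismatch such DNA stay open too, with 5 of the 6 genes lower, since probe sequences were not used here. Of these, Tdp1 has a 2nd probe set (mean 6.72) that changed by 0.01. An effect of the Psen1 mutation itself is confounded with the group and was not tested.

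Choroid plexus genes were high on homozygous replicate 1 and non-Tg replicate 3, by a median of 1.47 log2 over the other 7 arrays for 16 markers, led by Kcnj13 (3.5) and Ttr (3.27), whose mean was 13.86 on the 2 arrays. Transgene zygosity as the whole reason is argued against, since non-Tg replicate 3 carries no transgenes. Homozygous replicate 1 exceeded the higher of homozygous replicates 2 and 3 by 1.45 ± 0.83 log2 (SD over the 16 markers). It was picked as 1 of the 2 highest arrays, which favours such a gap, so the gap is no test of zygosity. Choroid plexus tissue left on the hippocampi is a candidate source that cannot be told apart from a change within the tissue: the log2 ratio of the excess on the 2 arrays had an SD of 0.52 over the markers, where under 0.5 was set for 1 common ratio and over 1 against it. How the hippocampi were trimmed is not given in the sources used here.

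Unfolded protein response genes were lower in homozygous than in hemizygous mice, by a mean of -0.16 log2. Choroid plexus carry-over is argued against, as the mean did not shrink with the choroid plexus score as a covariate, at -0.19. Its SE over genes was 0.029, which does not measure the spread between arrays, since genes of a list vary together. Without homozygous replicate 1, the choroid-rich array of these 2 groups, the mean was -0.21. A single array is argued against too: leaving out each homozygous or hemizygous array kept the mean between -0.21 and -0.12. The non-Tg arrays do not enter that mean. The hemizygous list mean (0.095) lay 0.13 ± 0.07 log2 (SD between arrays) above the nearer of the homozygous (-0.064) and non-Tg (-0.031) means. A change graded with transgene dose would place the hemizygous mean between the others. The values cannot decide this, because the hemizygous rise may itself come from a chance split. For hemizygous against non-Tg mice the exact permutation test of the list mean gave p = 0.1. A chance split cannot be told apart, because an exact permutation test of 3 against 3 arrays gave p = 0.1, two-sided, the smallest it allows. An effect of dose that is not graded was not tested and stays open.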

How the results depend on the processing

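The 2 alternatives on choroid plexus were chosen after seeing the data. Snapc1 stayed called under every alternative that gave it a value, in each of the 3 contrasts that called it. Across 24 calls of named genes, 171 of 265 alternatives without a left-out array kept the call and 94 lost it, and 60 of 216 leave-outs kept it and 156 lost it, all in the same direction. The counts moved with the processing as follows. Homozygous against non-Tg (3 genes) gave 11 with an intensity trend, 5 after quantile normalization, 40 in the upper 50% by mean (12 higher and 28 lower) and 1 without the 2 choroid-rich arrays. Hemizygous against non-Tg (6) gave 11 with a trend, 3 with a robust fit, 2 over all probe sets, 2 for the groups compared alone, 3 at a fold of at least 1.5, 1 without the 2 arrays and 2 with the choroid plexus score as a covariate. Both 3xTg groups against non-Tg (15) gave 24 in the upper 50%, 4 over all probe sets, 7 at a fold of 1.5, 1 without the 2 arrays and 2 with the covariate. The F test (2) gave 15 with a trend, 13 in the upper 50% and 0 without the 2 arrays. Homozygous against hemizygous stayed at 0. Centring on the median turned the 2 higher and 4 lower hemizygous calls into 3 and 3, and quantile normalization gave 3 higher and 4 lower. By construction the upper 50% tests fewer genes, all probe sets more, and a left-out array leaves fewer arrays; beyond that the cause was not tested.

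Leaving out 1 array at a time gave 2 to 4 genes in homozygous against non-Tg, 2 to 4 in hemizygous against non-Tg, 0 to 0 between the 3xTg groups, 2 to 4 in both 3xTg groups against non-Tg and 1 to 3 for the F test. Lists called were 4 to 9, 7 to 13, 7 to 12 and 7 to 12 in the 4 contrasts in that order. The similarity r was 0.536 to 0.705, where unchanged groups would give 0.447 without a 3xTg array and 0.6 without a non-Tg array. For called genes on chromosome 12, both 3xTg groups against non-Tg, p was 0.00316 to 0.125 (5 of 9 leave-outs lost the call). For called genes among the nearest to Psen1, both 3xTg groups against non-Tg, p was 0.02 to 1.

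List counts were 0 in all 4 contrasts with an estimated correlation and with fry. In the upper 50% they were 1 of 6 in homozygous and 4 of 10 in both 3xTg groups against non-Tg. Without the 2 choroid-rich arrays 13 lists were called between the 3xTg groups, 5 of them among the 8, and 5 in both 3xTg groups against non-Tg, 3 of them among the 10. For called genes among the nearest to Psen1, both 3xTg groups against non-Tg, p was 1.2e-05 with 200 nearest genes, 0.0239 in the upper 50%, and 1 with 50 nearest genes, with the replicate block or without the 2 choroid-rich arrays. Turned in direction were endothelium in homozygous against non-Tg (adjusted p 0.776 without the 2 arrays, 1.8e-04 to 0.763 on leaving out 1 array) and choroid plexus in hemizygous against non-Tg (0.931 with the covariate). Genes near 0 also changed sign: Pecam1 in homozygous against non-Tg (0 without the 2 arrays, 0 to 0.21 on leave-outs), Mapt in hemizygous against non-Tg (0.01 without the 2 arrays, 0 with the covariate, -0.05 to 0.02 on leave-outs), App in hemizygous against non-Tg (-0.02 to 0 on leave-outs) and between the 3xTg groups (-0.02 to 0.01), and Thy1 between the 3xTg groups (0 with the covariate). The cause was not tested.

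Replicate numbers are shared between groups in the labels, which do not say that they pair the mice. Same-numbered arrays correlated at -0.149 to 0.153 in their deviations, 3 of 9 pairs over 0.1, and 5 of 9 arrays correlated best with an array of their own number, 1 of them in both other groups, so not every array did. With the replicate block 1 gene was called in homozygous against non-Tg, 1 in hemizygous against non-Tg, 0 between the 3xTg groups, 3 in both 3xTg groups against non-Tg and 1 by the F test, with 9, 12, 10 and 11 lists.

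A change of pseudocount was not run, since the table is on a log scale. Signal over background could not be judged, as detection calls were not used here, and low values such as Eps8l1 at 6.11 are less certain.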

Other observations

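The scan of neighbouring genes below was chosen after the results were seen, while the lists and their tests were planned. Lists of further hippocampal cell types and neuronal gene groups are given as mean deviations ± SD over 3 arrays. CA1 pyramidal cell markers were at -0.052 ± 0.067 in homozygous, -0.005 ± 0.025 in hemizygous and 0.057 ± 0.03 in non-Tg mice. Neurogenesis genes were at -0.035 ± 0.033, -0.02 ± 0.111 and 0.055 ± 0.021, and neuropeptide genes at -0.007 ± 0.08, -0.045 ± 0.046 and 0.052 ± 0.098, in the same order. Dentate granule cell markers were at 0.006 ± 0.032, 0 ± 0.029 and -0.006 ± 0.055, and general astrocyte markers at -0.017 ± 0.056, 0.014 ± 0.039 and 0.002 ± 0.003. None of these 5 lists was called in any of the 4 contrasts.

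Single members of those lists, picked after their values were seen, passed adjusted over the list alone in both 3xTg groups against non-Tg, with 0 over all genes by limma. Among CA1 markers these were Spink8 (-0.79 ± 0.17 log2, SE), Dcn (-0.32 ± 0.08, also in the meningeal list, which was lower in 17 of 17 genes) and Man1a (0.2 ± 0.06). Among neuropeptides they were Crh (-0.2 ± 0.05), Grp (-0.2 ± 0.05) and Gal (-0.28 ± 0.08). For neurogenesis it was Sox11 (-0.45 ± 0.08), which lies on chromosome 12.

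Neighbouring genes that differ together may mark blocks of DNA from another strain. Windows of 50 neighbouring genes were scanned for genes at an unadjusted p under 0.001 in both 3xTg groups against non-Tg. The highest window held 5, where the 95th percentile of the highest window in 1000 shuffled gene orders was 4. It lay on chromosome 12 and held Kcnf1, Hpcal1, Gm9866, Sox11 and Adi1, 1 higher and 4 lower, and it was the 1 stretch above that level. Kcnf1 and Adi1 belong to the called genes of that chromosome. Hpcal1, Gm9866 and Sox11 belong to its uncalled genes counted above at the same p. The scan therefore reuses these genes and is not separate evidence. Which strains contributed DNA was not tested.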
